A study of Mus musculus with 6 samples.

How the data were processed

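Colon and liver RNA of 3 groups of male C57BL/6J mice was measured on Affymetrix Mouse Genome 430 2.0 arrays: control mice (CON), mice given dextran sodium sulphate (DSS), and mice given the same polymer and a parsley diet (DSSPAR). Each array held pooled RNA of 7 mice, labelled from 15 µg of total RNA, per the labels' protocols. There was 1 array per group and tissue, so 6 arrays made 6 groups of 1, taken from the group and tissue named in each sample's labels.

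The deposited values are intensities, 1 per probe set and array, on a linear scale, and were made with MAS5, the Affymetrix method that scales each array by a single factor, per the submitters' processing notes. The version and the scaling target are not given in the sources used here. All values were positive. With 2% of probe sets trimmed at each end, the mean intensity was 106.2, 111.0 and 110.2 in colon CON, DSS and DSSPAR and 499.8 in each liver array, so the tissues were scaled apart and were analysed apart. Detection calls were not used here. Every value column was matched to its sample by the labels, and 0 columns were left unused.

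Probe sets were named through the platform annotation. Of 45101 probe sets, 34958 carried 1 gene symbol, 932 carried several and 9211 were not listed. Probe sets with several symbols or not listed stayed unnamed and out of gene counts. Of those with 1 symbol, 34754 were found through their Entrez identifiers in the gene table used here, and 0 symbols needed an update. They covered 18194 genes. A gene with several probe sets was represented by the probe set of highest mean log2 intensity over the tissue's 3 arrays, and the share of called genes whose probe sets above the floor lay all on 1 side is reported per comparison.

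The scaling of the deposited intensities was kept. A floor was set at the median intensity of a tissue's 3 arrays. A gene entered a comparison if at least 1 of its 2 arrays lay above the floor, and values under the floor were raised to it, so a fold against a floored array is a lower bound. Log2 ratios were computed for 3 comparisons per tissue: DSS against CON, DSSPAR against DSS and DSSPAR against CON. Comparisons that share an array share its chance values. With 1 array per group there are no residual degrees of freedom, so no test was run and no p-value is given. Genes past 2-fold were counted in each direction. The number of arrays limits the precision.

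The spread between probe sets of 1 gene was estimated from the interquartile range of the difference between the log2 ratios of its 2 brightest probe sets, and taken as the noise of a value in simulations. It leaves out differences between pools and between arrays. The share of genes nearer to CON in DSSPAR than in DSS was computed over genes at least 2-fold off in DSS, with an exact Clopper-Pearson 95% interval. It was computed again with genes chosen on 1 probe set and measured on another, and in arrays simulated with the DSS effect fully kept or with no group effect. The share of the DSS effect kept in DSSPAR was a ratio of covariances across genes in which the 2 values of a gene came from different probe sets, with an interval from 1000 resamplings of genes. Pearson and Spearman correlations between tissues were computed across genes.

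Before the data were examined, 53 gene lists of pathways, processes and cell type markers were fixed, 37 for colon and 41 for liver, with 1251 genes, of which 1096 were on the array under 1 symbol. A list with at least 4 measured members was described by its median log2 ratio, by its members past 2-fold and by the percentile of that median among 10000 random lists of the same size, matched on mean intensity in 10 bins. A list stood apart when its percentile lay under 2.5 or over 97.5. The rule for naming genes was fixed at the same time. It takes, per comparison, the 10 genes with the highest and the 10 with the lowest log2 ratio whose brighter array lay at or above the 60th percentile and whose measured probe sets all shared the sign. It adds up to 4 members of each list with the largest ratios and lets a gene so named be followed in the other comparisons and in the other tissue. Predicted gene models counted among the 10 but were not named.

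Alternatives fixed at the same time were a floor at the 75th percentile, no floor, arrays centred on their own medians, quantile normalization within a tissue, the mean over a gene's probe sets, leaving out probe sets of shared type (identifiers ending in _s_at, _x_at or _a_at), a 3-fold threshold, and genes chosen on 1 probe set and measured on another. Centring on the median of probe sets above the floor and leaving out exocrine pancreas genes were added after the data were seen. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

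The procedure was tested on simulated data with 200 changed genes, drawn from genes whose mean log2 intensity lay over 2-fold above the floor. The noise was the spread between probe sets, equal at all intensities, with none between pools or arrays. The shares below therefore do not cover calls caused by pools, by arrays or by the larger noise of dim genes. For DSS against CON in colon, over 11570 genes, 100.0% of genes changed 4-fold and 52.0% of those changed 2-fold passed the 2-fold threshold, as did 0.0176% of unchanged genes. In liver, over 12101 genes, these shares were 99.0%, 48.0% and 0.504%. A simulated kept share of 0.6 was estimated as 0.59 in colon over 4866 genes and as 0.64 in liver over 4870 genes. No noise of a pool was simulated, so the effect of the shared CON array on this share was not tested.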

Results

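Gene expression was measured in colon and liver of male C57BL/6J mice, 7 weeks old, on Affymetrix Mouse Genome 430 2.0 arrays, which read a gene through 1 or more sets of short probes. Control mice (CON) had a basal diet and plain water. A second group (DSS) drank 1.5% (w/v) dextran sodium sulphate, a polymer that injures the colonic epithelium and causes colitis, after 7 days of plain water. The remaining group (DSSPAR) ate the basal diet with 2% parsley throughout and drank the same 1.5% dextran sodium sulphate. The treatment protocols gave 10 days on the polymer for DSS and 9 days for DSSPAR, so by these protocols the diet and 1 day of exposure differed together. The growth protocol gives 9 days, worded after the DSSPAR group alone, and does not settle the duration for DSS. RNA of the 7 mice of a group was pooled, and each group had 1 array per tissue, 6 arrays in all. Every difference below therefore compares 2 pools, has no replicate check and carries no p-value, and the number of arrays limits its precision.

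The median probe set intensity was 27.3 in colon CON, 25.8 in colon DSS and 22.5 in colon DSSPAR, and 107.0, 96.7 and 86.5 in the liver arrays in the same order. Levels were not compared between the tissues, whose arrays were scaled apart. The floor, the median intensity of a tissue's 3 arrays, was 25.1 in colon and 96.6 in liver, and 47.3% to 52.7% of probe sets per array lay above it. Of 44 probe sets of olfactory receptors, which neither tissue should express, at most 2.27% lay above the floor in a colon array and 15.9% to 27.3% in a liver array. A fold against an array at or under its floor is given as "at least". Pairs of probe sets for 1 gene disagreed with a robust SD of 0.39 log2 units in colon and 0.52 in liver for the ratio of DSS to CON, so a 2-fold difference is more securely read in colon. The median shift of all probe sets was -0.20 log2 for DSSPAR against DSS and -0.28 for DSSPAR against CON in colon. In liver it was -0.15 for DSS against CON, -0.16 for DSSPAR against DSS and -0.31 for DSSPAR against CON. Among probe sets above the floor these shifts stayed between -0.10 and 0.05.

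The comparison of DSS with CON in colon addressed what the colitis did to the tissue. Genes of innate defence were far higher in DSS. S100a8 and S100a9, which encode the neutrophil protein calprotectin, were at least 82.0-fold and at least 33.4-fold higher, and Slpi, a secreted inhibitor of leukocyte proteases, was 49.0-fold higher (intensity 2050 against 41.9). Clca4b was 79.4-fold higher, Lrg1 at least 35.5-fold, the collagenase gene Mmp13 25.5-fold and Lcn2, whose product binds bacterial siderophores, at least 19.8-fold. The lowest genes included enzymes and transporters. Cyp2c55 was 40.4-fold lower, Cyp2c65 24.8-fold and Cyp4b1 at least 20.4-fold, all cytochrome P450 genes. The bile acid transporter genes Slc51a and Slc10a2 were at least 14.9-fold and at least 8.38-fold lower, the sulphate transporter gene Slc13a1 at least 9.35-fold and Fabp2, a fatty acid binding protein of enterocytes, 7.05-fold. Acaa1b was at least 10.2-fold lower, Ugt2b5 at least 9.48-fold, Prkg2 9.07-fold and Hkdc1 8.45-fold. Of 11952 genes measured, 619 were at least 2-fold higher and 236 at least 2-fold lower in DSS, with 116 and 35 past 4-fold.

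Gene groups were fixed before the data were examined. The percentile given for a group is that of its median log2 ratio among 10000 random lists of the same size matched on mean intensity, which describes these arrays only. Of 17 measured macrophage and monocyte markers, 14 were at least 2-fold higher and none lower (median 1.75, percentile 100), among them Chil3 (at least 11-fold), the lysosomal gene Cd68 (at least 5.99-fold, but a log2 ratio of 0.53 with the floor at the 75th percentile) and the complement gene C1qa (4.66-fold). Of 27 cytokine and chemokine genes 14 were higher and none lower (median 1.71, percentile 100), with the chemokine genes Cxcl9 at least 19.7-fold, Ccl8 18.5-fold and Cxcl5 at least 16.7-fold higher. Of 26 interferon-stimulated genes 17 were higher and none lower (median 1.58, percentile 100), including the GTPase genes Iigp1 (8.36-fold), Gbp2 (6.46-fold) and Gbp6 (5.78-fold). Among 21 genes of antimicrobial and mucosal defence 14 were higher and 1 was lower (median 1.74, percentile 100), with Pla2g2a, a bactericidal phospholipase, at least 12-fold and Retnlb, a goblet cell protein, 6.87-fold higher, while the ribonuclease gene Ang4 was 3.41-fold lower. Proliferation genes were higher in 19 of 29 cases and lower in none (median 1.27, percentile 100), for example Birc5 (5.39-fold) and Cdk1 (3.29-fold).

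Connective tissue and vessel genes were also higher in the DSS colon. Of 17 matrix metalloproteinase and inhibitor genes 8 were higher and 1 was lower (median 0.99, percentile 100), with Mmp3 at least 19.2-fold and Mmp10 at least 12.4-fold higher. Fibroblast and matrix genes were higher in 8 of 20 cases (median 0.94, percentile 100), including the collagen genes Col5a2 (2.70-fold) and Col5a1 (2.59-fold) and the collagen crosslinking enzyme Lox (at least 3.93-fold). Endothelial markers were higher in 7 of 14 cases (median 0.96, percentile 100), including the adhesion molecules Vcam1 (4.91-fold) and Selp (at least 3.38-fold). Markers of other tissues were higher in the same array: squamous epithelium markers in 7 of 12 cases with 1 lower (median 1.03, percentile 100) and adipocyte markers in 3 of 9 (median 0.39, percentile 97.6). The adipocyte group fell short of standing apart with arrays centred on their medians (percentile 93.0). Of its higher members, Car3 and Fabp4 did not have all their probe sets on the same side of CON. Of 33 absorptive colonocyte genes 8 were lower and 1 was higher (median -0.43, percentile 0.0). Of 15 crypt base and stem cell genes 13 lay below CON (median -0.37, percentile 0.08), though the stem cell marker Lgr5, 2.90-fold lower, alone passed 2-fold. Goblet cell and mucus genes (median -0.031, percentile 16.4) and tight and adherens junction genes (median -0.068, percentile 9.04) did not stand apart from random lists. Of 36 measured groups 17 stood apart on the high side and 3 on the low side, outside the middle 95% of random lists.

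Pancreatic enzyme genes moved with these groups in the colon DSS array. Of 15 exocrine pancreas genes, 12 were at least 2-fold higher in DSS (median 2.89, percentile 100), for example the trypsinogen gene Prss2 (at least 23.2-fold) and the chymotrypsinogen gene Ctrb1 (at least 18.7-fold), and Reg2, a secreted lectin gene of the pancreas and inflamed gut, was at least 26.4-fold higher. Without exocrine pancreas genes the counts were 607 higher and 236 lower, and the antimicrobial group, which shares members with them, had a median of 1.43 (percentile 100). Among called genes with several probe sets above the floor, 93.1% had all of them on 1 side of CON, against 57.1% of all genes with several. With arrays centred on their medians the split was 704 higher and 191 lower.

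**Figure D1:**
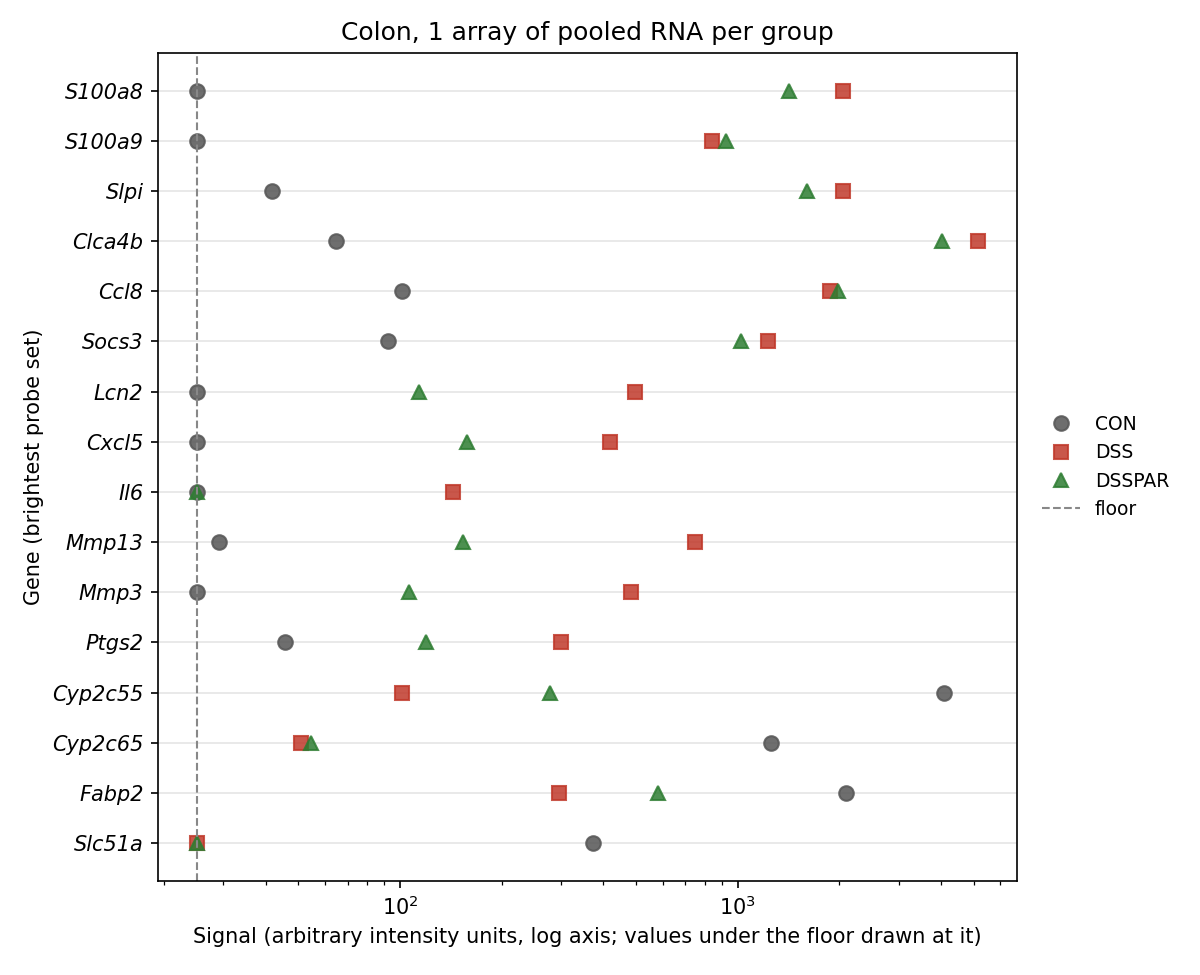
Intensity of 16 colon genes (arbitrary units, log axis) in the arrays of CON (circles), DSS (squares) and DSSPAR (triangles), 1 array of pooled RNA each, with values under the floor of 25.1 (dashed) drawn at it and levels not comparable between genes. S100a8 stood at 18.5 in CON, 2057 in DSS and 1423 in DSSPAR, while Mmp13 and Cyp2c55 were nearer to CON in DSSPAR than in DSS, 4.85-fold lower and 2.74-fold higher than in DSS.

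The comparison of DSSPAR with DSS in colon addressed how the colitis group fed parsley differed from the one without it. It cannot part the diet from the exposure or from differences between pools. Genes of tissue remodelling and of inflammatory signals were lower in DSSPAR. Mmp13 was 4.85-fold lower, Mmp3 4.54-fold and Mmp10 3.63-fold, and 8 of 17 matrix metalloproteinase and inhibitor genes were at least 2-fold lower with none higher (median -0.83, percentile 0.0). Il6, the cytokine that drives acute phase synthesis in liver, was at least 5.71-fold lower, the monocyte chemokine genes Ccl7 and Ccl2 at least 3.28-fold and 3.25-fold, and Ptgs2, the inducible cyclooxygenase, 2.52-fold. With the floor at the 75th percentile Il6 and Ccl2 fell short of 2-fold, at log2 ratios of -0.46 and -0.44. Of 26 cytokine and chemokine genes 9 were lower and none higher (median -0.36, percentile 0.03). Lcn2 was 4.35-fold lower and Saa3, a serum amyloid gene, 2.96-fold lower, and Ang4 was 3.02-fold higher, within an antimicrobial group of which 4 of 21 members were lower and 2 higher (median -0.21, percentile 0.01). Without exocrine pancreas genes, among them its member Reg1, that median was -0.14 (percentile 0.37).

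Genes of nerves, vessels and connective tissue were also lower in the DSSPAR colon than in DSS. All 13 enteric neuron and glia markers lay below DSS (median -0.54, percentile 0.03). In this array pair 37 of 3220 genes over 50 kb long were at least 2-fold lower and 8 higher. Among 1420 genes up to 5 kb, 31 were lower and 7 higher, so long genes did not pass 2-fold more often. The median log2 ratio was -0.055 for the long genes and 0.031 for the short ones, and random lists were not matched on length. Endothelial markers were lower in 3 of 14 cases (median -0.62, percentile 0.0), among them Selp (2.76-fold), Eng (2.49-fold) and Plvap (2.49-fold), and fibroblast and matrix genes in 3 of 20 (median -0.58, percentile 0.0). Markers of adipocytes (2 of 9 lower, median -0.39, percentile 0.79) and of squamous epithelium (2 of 12 lower, median -0.41, percentile 0.76) were lower too, the squamous group not standing apart without probe sets of shared type (median -0.26, percentile 13.3). Of 29 proliferation genes 28 lay below DSS, with 1 past 2-fold (median -0.32, percentile 0.0). Macrophage and monocyte markers (median -0.26, percentile 0.64) had 1 member of 17 at least 2-fold lower, and interferon-stimulated genes did not stand apart (median -0.10, percentile 7.26). On the higher side, 29 of 32 absorptive colonocyte genes lay above DSS (median 0.28, percentile 99.96), with Cyp2c55 2.74-fold higher and Fabp2 at a log2 ratio of 0.97. Oxidative phosphorylation genes lay above DSS in 56 of 60 cases (median 0.31, percentile 100), in an array pair where shorter genes tended to have higher ratios (Spearman correlation with gene length -0.0965) and the 18S ribosomal RNA control read 390.4 in DSSPAR against 4018 in DSS. Genes of the antioxidant regulator NRF2 and of glutathione lay above DSS in 23 of 33 cases (median 0.21, percentile 99.6), for example the quinone reductase gene Nqo1 (1.98-fold) and the carbonyl reductase gene Cbr3 (1.94-fold). The NRF2 group fell short of standing apart after quantile scaling (median 0.12, percentile 94.2), and the neutrophil markers, at a median of -0.53 (percentile 0.05), did so with the floor at the 75th percentile (median -0.15, percentile 14.0). The heat shock, immediate early and smooth muscle groups, with medians of -0.12, -0.16 and -0.13, changed sign when arrays were centred on their medians.

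Of 11730 genes, 46 were at least 2-fold higher and 146 at least 2-fold lower in DSSPAR than in DSS, and none was 4-fold higher while 19 were 4-fold lower. The most strongly lower genes were those of the pancreas, Reg2 at least 26.4-fold, Prss2 at least 23.2-fold, Ctrb1 at least 18.7-fold, Cela2a at least 17.9-fold and Cpb1 at least 14.8-fold, and the exocrine pancreas group had 12 of 15 members lower (median -2.89, percentile 0.0). Without exocrine pancreas genes the counts were 46 higher and 134 lower. The highest genes were Ang4, Zbtb7b (2.90-fold, log2 ratio 0.25 with the floor at the 75th percentile), S100g, a calcium binding protein (2.85-fold), Cyp2c55 and Ttr, the thyroid hormone carrier transthyretin (2.68-fold). The split depended on scaling: it was 108 higher and 79 lower with arrays centred on their medians, and 70 and 97 with arrays centred on probe sets above the floor. Of called genes with several probe sets, 82.3% had all of them on 1 side, against 51.9% of all genes with several.

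Against CON, the DSSPAR colon again had calprotectin and other defence genes far higher. Clca4b was 62.2-fold higher than CON, S100a8 at least 56.7-fold, Slpi 38.3-fold, S100a9 at least 36.8-fold, Ccl8 19.6-fold and the cytokine signalling inhibitor gene Socs3 11.1-fold. Cyp2c65 was 23.1-fold lower, Cyp4b1 at least 20.4-fold, Slc51a at least 14.9-fold and Cyp2c55 14.7-fold. Macrophage and monocyte markers (13 of 16 higher, median 1.54), interferon-stimulated genes (18 of 26, median 1.28), cytokines and chemokines (13 of 22, median 1.14) and antimicrobial genes (10 of 19, median 1.00) all stood at percentile 100, with no member 2-fold lower. A member under the floor in both CON and DSSPAR leaves these counts, even if it was above the floor in DSS. For DSS against CON, 27 cytokine and chemokine and 21 antimicrobial genes were measured. The shares and medians against CON are therefore not directly comparable between DSS and DSSPAR, and can be too high in DSSPAR. Proliferation genes were higher in 8 of 29 cases (median 0.76, percentile 100). Fibroblast and matrix genes (median 0.29, percentile 95.3) and endothelial markers (median 0.11, percentile 85.3) did not stand apart from random lists against CON. Enteric neuron and glia markers lay below CON in 12 of 14 cases (median -0.42, percentile 0.36) and smooth muscle markers in 15 of 16 (median -0.40, percentile 0.0). Longer genes tended to have lower ratios in this array pair (Spearman correlation with gene length -0.207), and random lists were not matched on length. Genes of NRF2 and glutathione were higher in 5 of 33 cases and lower in none (median 0.41, percentile 99.98), including the glutathione transferase gene Gsta3 (3.78-fold) and Cbr3 (3.40-fold). In DSS against CON this group did not stand apart (3 of 34 higher and 1 lower, median 0.13, percentile 78.5). Gsta3 was already 2.74-fold and Cbr3 1.755-fold higher there. Crypt base and stem cell genes were lower in 4 of 15 cases (median -0.58, percentile 0.0), with Lgr5 3.47-fold lower. The other 3, Ascl2, Sox9 and Znrf3, fell short of 2-fold with arrays centred on their medians (log2 ratios -0.84, -0.90 and -0.73).

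Among 11808 genes, 415 were at least 2-fold higher and 248 lower in DSSPAR than in CON, and 890 and 121 with arrays centred on their medians. Of called genes with several probe sets, 83.5% had all of them on 1 side, against 56.9% of all genes with several. Without exocrine pancreas genes the counts were 415 and 248. The absorptive colonocyte median of -0.036 (percentile 1.03, 2 of 33 higher and 6 lower) turned positive when arrays were centred on their medians or on probe sets above the floor. The metalloproteinase group, at a median of 0.68 (percentile 100, 6 of 14 higher), no longer stood apart with the floor at the 75th percentile (median 0.029, percentile 51.1). This group had 17 measured members for DSS against CON, since members under the floor in both arrays of a comparison leave it.

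**Figure D2:**
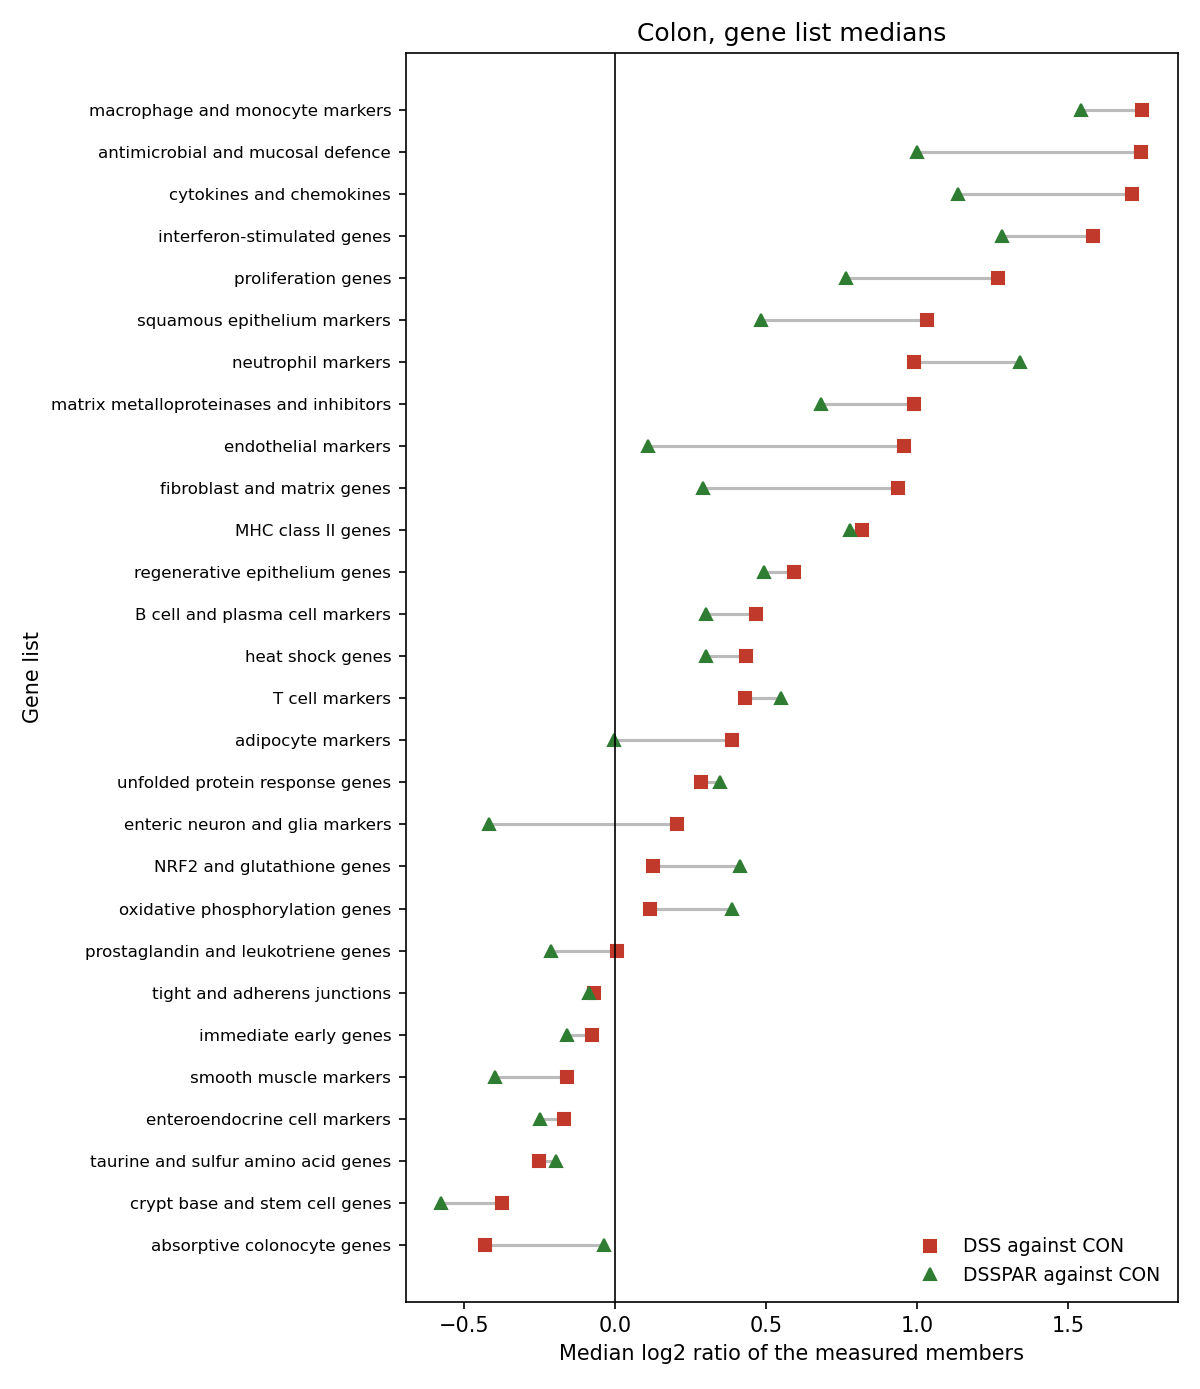
Median log2 ratio of the measured members of 28 colon gene lists for DSS against CON (squares) and DSSPAR against CON (triangles), for lists that stood apart in either, exocrine pancreas markers left out. A member under the floor in both arrays of a ratio is left out of its median, so members measured can differ between the 2 ratios. Endothelial markers stood at 0.96 in DSS and 0.11 in DSSPAR, macrophage markers at 1.75 and 1.54, and the DSSPAR medians of the absorptive, enteroendocrine, immediate early, prostaglandin, taurine and junction lists changed sign when arrays were centred on their medians.

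The return toward CON was measured over the genes at least 2-fold off in DSS. In colon, 695 of 855 such genes (81.3%, exact Clopper-Pearson 95% interval 78.5 to 83.9) were nearer to CON in DSSPAR than in DSS, 524 of 619 higher genes and 171 of 236 lower ones. Choosing genes on the DSS array favours such a return, and arrays simulated with a fully kept effect gave 61.9%. In arrays simulated with no group effect, 2 of 2 genes past 2-fold were nearer to CON. When a gene was chosen on 1 probe set and measured on another, 382 of 520 choices (73.5%, interval 69.4 to 77.2) in 384 genes were nearer to CON. Across 4814 genes with several probe sets, the estimated share of the DSS effect kept in DSSPAR was 74.4% (69.8 to 78.5, resampling genes). Genes are not independent replicates, and these intervals leave out the variation between pools. The kept share also takes both ratios against the same CON array. Chance differences of the CON pool therefore count as kept effect, and those of the DSS pool as return.

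In the liver, the comparison of DSS with CON addressed the response of a distant organ to colitis. Acute phase genes, whose products the liver secretes into blood during inflammation, were among those with the highest ratios. Lcn2 was 250.0-fold higher in DSS, Orm2, which encodes orosomucoid, 99.1-fold, and the metallothionein genes Mt2 and Mt1 70.8-fold and 46.5-fold. The serum amyloid genes Saa3 and Saa2 were 33.0-fold and 25.1-fold higher, S100a8 39.1-fold, the neutrophil protease gene Prtn3 44.4-fold and A2m, a protease inhibitor, 13-fold. Of 33 acute phase genes 25 were at least 2-fold higher and 2 lower (median 2.44, percentile 100). The lowest genes were Hamp2, a hepcidin gene, 17.8-fold, Cyp4a12a 13.7-fold, G6pc, the last enzyme of gluconeogenesis, 10.3-fold, Elovl3, a fatty acid elongase, 9.95-fold, and malic enzyme Me1 8.75-fold. The group of gluconeogenesis and glucocorticoid target genes did not stand apart (5 of 27 higher and 4 lower, median -0.11, percentile 16.0). Of 13034 genes, 616 were at least 2-fold higher and 548 lower, with 63 and 38 past 4-fold.

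Metabolic groups of the liver were lower in DSS. All 25 fatty acid and triglyceride synthesis genes lay below CON, 14 of them by 2-fold or more (median -1.05, percentile 0.0), including the acetyl-CoA carboxylase gene Acacb (5.82-fold), Thrsp (4.40-fold) and fatty acid synthase Fasn (4.02-fold). Cytochrome P450 genes of drug and steroid metabolism were lower in 10 of 33 cases and higher in 2 (median -0.70, percentile 0.0), with Cyp1a2, which oxidises caffeine, 3.51-fold lower and Cyp17a1, a steroid hydroxylase, 4.05-fold higher. Conjugating enzyme genes were lower in 14 of 37 cases and higher in 3 (median -0.65, percentile 0.0), for example Ugt2b38 (7.64-fold lower) and Gsta2 (6.02-fold lower), while the oestrogen sulphotransferase gene Sult1e1 was at least 5.0-fold higher (log2 ratio 0.40 with the floor at the 75th percentile). Amino acid and urea cycle genes were lower in 8 of 38 cases and higher in none (median -0.67, percentile 0.0), such as Oat (3.45-fold) and Hal (3.27-fold). Bile acid genes were lower in 3 of 26 cases and higher in 1 (median -0.48, percentile 0.0), with Cyp8b1, the sterol hydroxylase of cholic acid synthesis, 5.94-fold lower. Oxidative phosphorylation genes lay below CON in 53 of 60 cases, 1 by 2-fold (median -0.41, percentile 0.0). Cholesterol synthesis genes (median 0.0067, percentile 48.2) and interferon-stimulated genes (median 0.22, percentile 92.7) did not stand apart.

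Macrophage, Kupffer cell, neutrophil and cell cycle genes were higher in the DSS liver. Of 16 macrophage and monocyte markers 10 were at least 2-fold higher (median 1.32, percentile 100), among them the endotoxin receptor gene Cd14 (7.10-fold). Kupffer cell markers were higher in 4 of 12 cases (median 0.73, percentile 99.98), with the scavenger receptor gene Marco 10.4-fold higher, and neutrophil markers in 3 of 10 (median 0.61, percentile 99.8). Markers of T cells (median -0.26, percentile 20.2), markers of B and plasma cells (median -0.091, percentile 44.0) and MHC class II genes (median -0.020, percentile 52.0) did not stand apart, and the immunoglobulin gene Ighm was 8.68-fold lower. All 21 proliferation genes lay above CON, 8 by 2-fold (median 0.65, percentile 100). Of 41 groups 9 stood apart on each side. Probe sets of 1 gene disagreed more often than in colon. Of called genes with several probe sets 63.7% had all of them on 1 side, against 50.2% of all genes with several. With arrays centred on their medians the split was 854 higher and 349 lower.

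**Figure D3:**
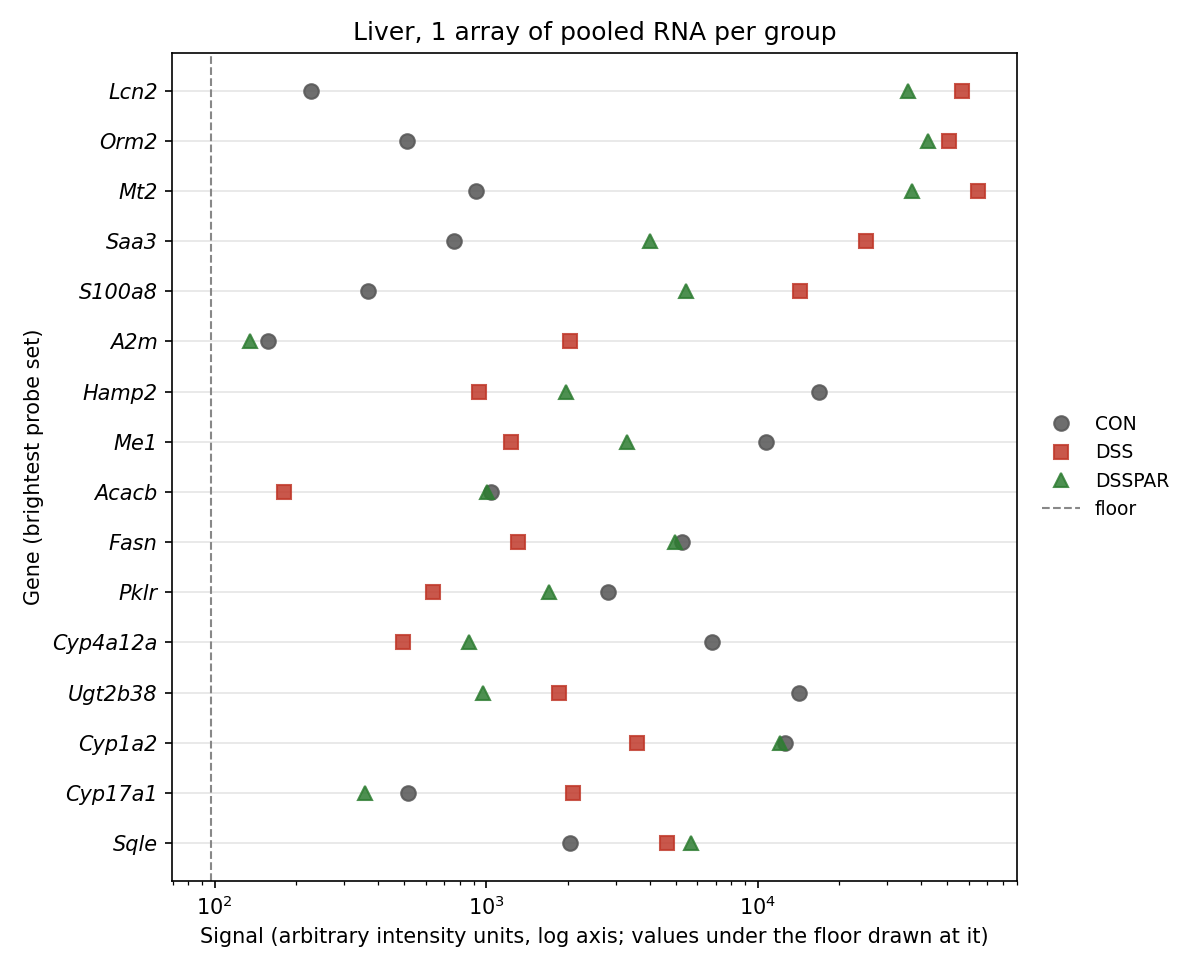
Intensity of 16 liver genes (arbitrary units, log axis) in the arrays of CON (circles), DSS (squares) and DSSPAR (triangles), 1 array of pooled RNA each, with the floor of 96.6 dashed and levels not comparable between genes. Lcn2 and Orm2 stayed 157.5-fold and 82.9-fold above CON in DSSPAR, whereas A2m was 15.1-fold lower and Acacb 5.63-fold higher in DSSPAR than in DSS.

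The comparison of DSSPAR with DSS in liver addressed how these groups differed in that organ, with the same limits as in colon. Genes of lipid synthesis were higher in DSSPAR: Acacb 5.63-fold, Fasn 3.79-fold, Pklr, a pyruvate kinase of the fed liver, 2.68-fold, and Me1 2.68-fold (log2 ratio 0.81 without probe sets of shared type). Of 25 fatty acid and triglyceride synthesis genes 24 lay above DSS, 9 by 2-fold or more (median 0.82, percentile 100). Acute phase genes were lower, 6 of 33 by 2-fold with 1 higher (median -0.61, percentile 0.0), led by A2m (15.1-fold) and Saa3 (6.21-fold), whereas Lcn2 and Orm2 had log2 ratios of -0.67 and -0.26. Macrophage and monocyte markers were lower in 3 of 16 cases (median -0.41, percentile 0.70), with Cd14 2.58-fold lower. S100a9 and S100a8 were 3.18-fold and 2.64-fold lower, while the neutrophil markers did not stand apart (3 of 13 lower, median -0.31, percentile 10.5). Spink1, a trypsin inhibitor, was 8.79-fold lower, Cyp17a1 5.82-fold and Sult1e1 at least 5.0-fold (log2 ratio -0.40 with the floor at the 75th percentile).

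Genes of amino acid, drug and sterol metabolism were higher in the DSSPAR liver than in DSS. Amino acid and urea cycle genes were higher in 4 of 38 cases (median 0.52, percentile 100), among them the aspartate aminotransferase gene Got1 (4.02-fold) and Hal (2.70-fold). Cytochrome P450 genes were higher in 4 of 32 cases and lower in 2 (median 0.52, percentile 100), with Cyp26a1, which degrades retinoic acid, 5.05-fold (log2 ratio 0.65 with the floor at the 75th percentile) and Cyp1a2 3.35-fold higher. Cholesterol synthesis genes were higher in 4 of 22 cases (median 0.51, percentile 100), bile acid genes in 2 of 25 (median 0.46, percentile 99.99) and conjugating enzyme genes in 8 of 37 with 3 lower (median 0.38, percentile 99.99). G6pc was 3.64-fold and the anion transporter gene Slc22a7 4.0-fold higher, while the gluconeogenesis and glucocorticoid group did not stand apart (4 of 27 higher and 2 lower, median 0.11, percentile 79.9). Ribosomal protein genes were lower in 6 of 37 cases (median -0.28, percentile 2.29) and did not stand apart after quantile scaling (median -0.027, percentile 23.2). In this array pair 109 of 1576 genes up to 5 kb long were at least 2-fold lower and 26 higher, and the 3'/5' signal ratio of Actb was 2.63 in DSSPAR against 3.53 in DSS. Of 12398 genes, 347 were at least 2-fold higher and 525 lower, against 674 and 332 with arrays centred on their medians. Of called genes with several probe sets 69.2% had all of them on 1 side, against 50.7% of all genes with several.

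Against CON, the DSSPAR liver had acute phase genes far higher, with 22 of 33 genes at least 2-fold higher and 2 lower (median 1.46, percentile 100). Lcn2 was 157.5-fold higher, Orm2 82.9-fold, Mt2 40.2-fold, Prtn3 35.4-fold, S100a8 14.8-fold and Saa2 13.4-fold. Macrophage markers (6 of 16 higher, median 0.84), Kupffer cell markers (5 of 12, median 0.79) and proliferation genes (10 of 22, median 0.89) stood at percentile 100. Cholesterol synthesis genes were higher in 5 of 22 cases and lower in none (median 0.80, percentile 100), including squalene epoxidase Sqle (2.78-fold), Msmo1 (2.41-fold) and Hmgcs1 (2.27-fold), although Msmo1 fell short of 2-fold without probe sets of shared type (log2 ratio 0.61). Ugt2b38 was 14.6-fold lower, Ces2b, a carboxylesterase, at least 8.92-fold, Hamp2 8.50-fold, Cyp4a12a 7.86-fold and Elovl3 6.06-fold. Oxidative phosphorylation genes lay below CON in 59 of 60 cases, 2 by 2-fold (median -0.50, percentile 0.0), in an array pair where shorter genes tended to have lower ratios (Spearman correlation with gene length 0.114) and the 3'/5' signal ratio of Actb was 2.63 against 3.55 in CON. A2m, Acacb and Fasn had log2 ratios of -0.21, -0.048 and -0.085. The fatty acid synthesis group (median -0.30, percentile 0.70, 2 of 25 lower) and the group of fatty acid oxidation and PPARA targets (median -0.26, percentile 1.0) turned slightly positive when arrays were centred on their medians. Of 12721 genes, 415 were at least 2-fold higher and 439 lower, against 1007 and 188 with arrays centred on their medians. Of called genes with several probe sets 68.8% had all of them on 1 side, against 49.85% of all genes with several.

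**Figure D4:**
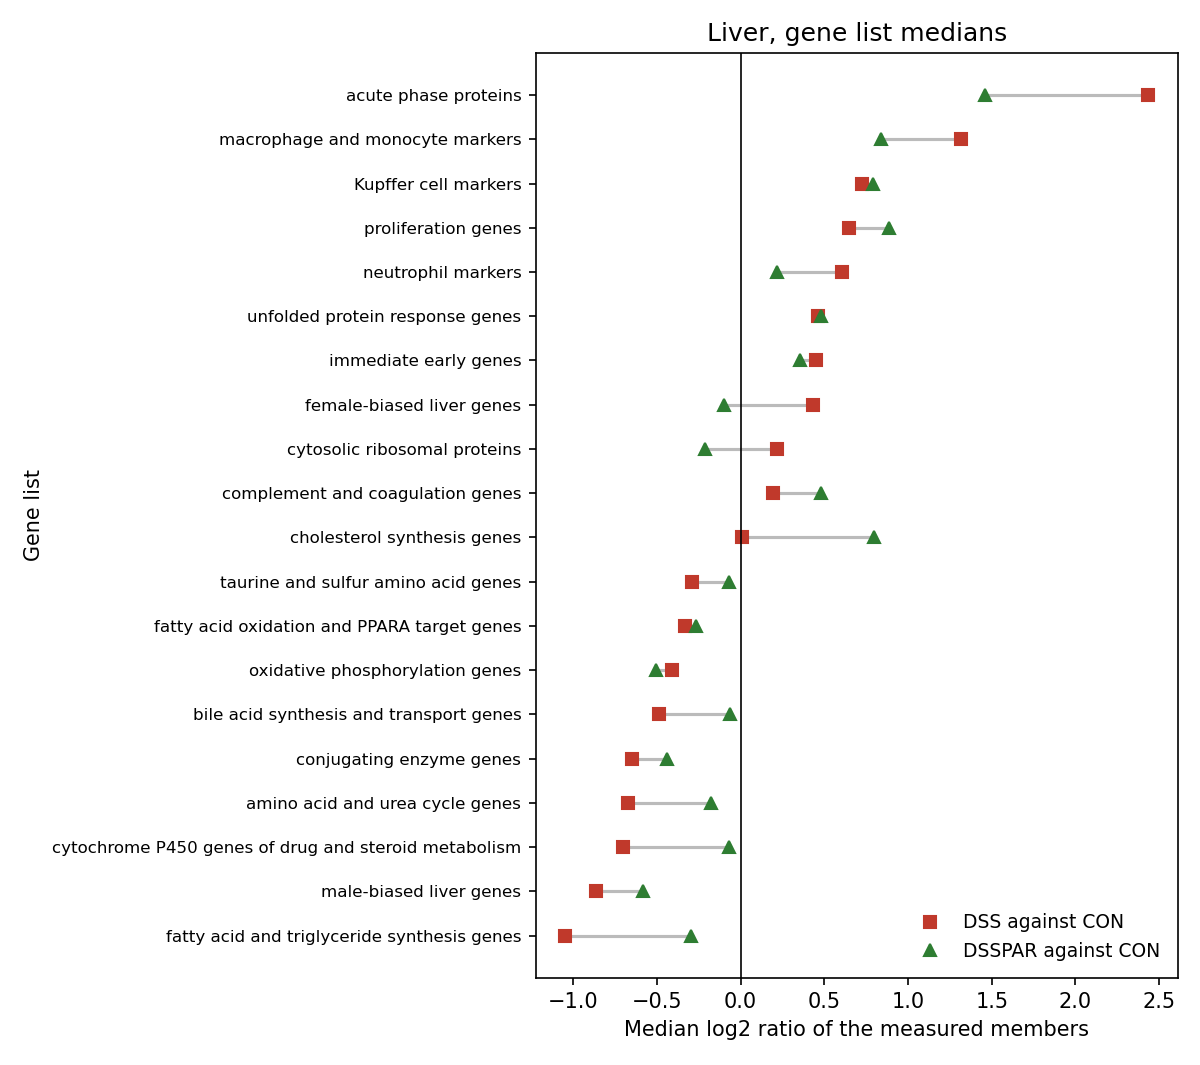
Median log2 ratio of the measured members of liver gene lists for DSS against CON (squares) and DSSPAR against CON (triangles), for lists that stood apart in either. Acute phase proteins stood at 2.44 in DSS and 1.46 in DSSPAR and fatty acid synthesis at -1.05 and -0.30, the latter and the DSSPAR median of fatty acid oxidation changing sign when arrays were centred on their medians.

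In liver, 985 of 1164 genes at least 2-fold off in DSS (84.6%, exact interval 82.4 to 86.7) were nearer to CON in DSSPAR, against 61.6% in arrays simulated with a fully kept effect. With no group effect simulated, 59 of 61 called genes (96.7%) were nearer to CON. Chosen on 1 probe set and measured on another, 508 of 779 choices (65.2%, interval 61.8 to 68.6) in 653 genes were nearer to CON. The estimated share of the DSS effect kept in DSSPAR was 49.3% (44.5 to 53.9) over 4603 genes. As in colon, chance differences of the CON pool count as kept effect and those of the DSS pool as return. This value cannot be told apart from what equally variable pools without a DSS effect would give.

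Several genes were higher in DSS than in CON in both tissues. S100a8, S100a9, Lcn2, Saa2, Saa3, Lrg1, Socs3, Mt1 and Mt2 were among 119 genes at least 2-fold higher in both tissues, against 25.2 if the tissues were independent. In colon, Mt2 was 2.46-fold and Saa2 2.01-fold higher, and in liver Lrg1 was 3.82-fold higher. Some of these calls were lost under an alternative: Socs3 in liver and Mt1 in colon without probe sets of shared type (log2 ratios 0.93 and 0.45), Saa2 in colon after quantile scaling (0.92). Acaa1b, Ces2b and Cyp2c55 were among 16 genes lower in both, against 6.89, though Cyp2c55 in liver had a log2 ratio of -0.14 with the floor at the 75th percentile. Opposite calls numbered 14 for genes higher in colon and lower in liver and 10 for the reverse, against 19.4 and 8.95. Across 10766 genes the log2 ratios of DSS to CON had a Pearson correlation of 0.21 (95% interval 0.19 to 0.23) and a Spearman correlation of 0.14, and without a floor the Pearson correlation was 0.065. Those of DSSPAR to DSS had -0.010 and -0.027 across 10463 genes. The pools of both tissues came from the same groups of mice, and genes are not independent replicates.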

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

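The tests of pancreatic tissue, of expression by the inflamed colon and of the shorter exposure to the polymer were chosen only after the result was seen; the other tests were written beforehand. Differences between the tissues rest on 1 array per group and were not tested.

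Several genes went opposite ways in the tissues. Ang4, a secreted antimicrobial ribonuclease, had a log2 ratio of DSS to CON of -1.77 in colon and 1.04 in liver, the latter 0.36 with the mean over probe sets, and of DSSPAR to DSS of 1.59 in colon and -1.50 or lower in liver, where DSSPAR lay under the floor. Cxcl9, an interferon-induced chemokine, had at least 4.30 in colon, where CON lay under the floor, and -1.61 in liver for DSS against CON. Cyp7b1, an oxysterol hydroxylase, had at least 1.75 in colon, CON again under the floor, and -1.62 in liver. Slc10a2, the bile acid uptake transporter, had -3.07 or lower in colon, where DSS lay under the floor, and 1.39 in liver, the latter 0.099 with the floor at the 75th percentile, so its higher value in liver depends on the floor.

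Probe sets without a single gene name were left out of the gene counts, yet 114 of 10092 were at least 2-fold higher in DSS than in CON in colon and 118 in liver, against 86 and 166 at least 2-fold lower. Of the colon ones, the probe set with the largest ratio had an intensity of 4.45 in CON, 2876 in DSS and 0.166 in DSSPAR, and the next 4.76, 935.0 and 5.15. Both lay under the floor in CON and DSSPAR, a pattern shared with pancreatic enzyme genes such as Prss2, and the genes they read are not known here. Of the liver ones, the probe set with the largest ratio had 176.9, 2446 and 2844.

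Pancreatic enzyme genes were high in the colon DSS array alone, with Prss2 at 581.1 against 12 in CON, Ctrb1 at 468.4 against 1.55 and Cela2a at 450.1 against 5.46. Leaving out Zg16, which goblet cells also express, 12 of 14 measured markers (85.7%) were at least 2-fold higher in DSS than in both other colon arrays, while Cela1 and Clps, both above the floor in CON, were not. This share restates the pattern and decides nothing. Islets stay open: Ins2 read 30.4 in DSS, just over the floor of 25.1 (log2 ratio 0.28 with CON at the floor), while Iapp, another islet gene, read 14.3 in DSS and 29.2 in CON. The markers' median log2 ratio of DSSPAR to CON was 0.0, so expression by the inflamed colon would have had to end in DSSPAR. Macrophage and monocyte markers stayed above CON there (median 1.54). Of 26 cytokine and chemokine genes, 9 were at least 2-fold lower than in DSS and none higher. Each group had 1 pool, so such an end and pancreatic tissue in the DSS pool cannot be told apart.

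Most genes off in DSS were nearer to CON in DSSPAR. Choosing genes on the shared DSS array gave 61.9% in colon and 61.6% in liver in arrays simulated with a fully kept effect. With no group effect simulated, 2 of 2 called genes in colon and 59 of 61 in liver were nearer to CON. Genes called by noise alone would thus mostly return. By the bound of 60% set beforehand, probe set noise in this choice does not account for the whole. Tests on separate probe sets gave 73.5% in colon (interval 69.4 to 77.2) and 65.2% in liver (61.8 to 68.6). These intervals treat choices as independent, although a gene could be chosen on each of its probe sets, so the narrow margin in liver is insecure. Separate probe sets remove the noise of a probe set, not that of a pool or an array, so a chance difference between pools or arrays stays open in both tissues. A shorter exposure of DSSPAR, 9 days against 10 in the treatment protocols, cannot be told apart from the parsley diet, and the growth protocol leaves open whether the durations differed at all. The effect of parsley itself, named by the design, likewise stays open and untested.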

How the results depend on the processing

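Centring on probe sets above the floor and leaving out exocrine pancreas genes were chosen only after the results were seen; the other alternatives were fixed beforehand. Of 108 list medians that stood apart, 82 did so under every alternative run and 97 kept their direction. No named gene changed direction, and 117 values of named genes fell short of 2-fold under an alternative, 60 of them with the floor at the 75th percentile. Dim genes limit the results, since without a floor the noise of dim values enters the counts. The floor is a median by definition, so the 47.3% to 52.7% of probe sets above it do not measure how many genes were dim. The spread between pools, with 1 array per group, was not measured and no alternative covers it. No paired analysis was possible because each group had 1 array per tissue and the labels give no replicate numbers. The mean over probe sets moved no count by over 1.5 times, nor did leaving out exocrine pancreas genes.

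Counts of genes higher and lower are given for DSS against CON, DSSPAR against DSS and DSSPAR against CON, first in colon, then in liver. With the floor at the 75th percentile, which leaves fewer genes, they were 274 and 102, 20 and 51, 208 and 87 in colon and 275 and 195, 150 and 230, 173 and 113 in liver. Without a floor they were 1850 and 1719, 1295 and 1532, 1594 and 1842 in colon and 2076 and 2750, 1934 and 2632, 1590 and 2991 in liver. With a 3-fold threshold they were 210 and 62, 1 and 35, 125 and 63 in colon and 140 and 90, 35 and 68, 85 and 54 in liver. With arrays centred on their medians, counts that moved by over 1.5 times were 108 and 79 for colon DSSPAR against DSS, 890 and 121 for colon DSSPAR against CON, 349 lower for liver DSS against CON, 674 and 332 for liver DSSPAR against DSS and 1007 and 188 for liver DSSPAR against CON. For colon DSSPAR against DSS, quantile normalization gave 92 lower, and centring on probe sets above the floor 70 and 97.

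The share of colon genes nearer to CON in DSSPAR, 81.3%, was 78.2% with the higher floor, 76.1% without a floor, 72.2% with arrays centred on their medians, 78.1% with centring on probe sets above the floor and 73.5% with genes chosen on 1 probe set and measured on another. The liver share, 84.6%, was 90.0%, 76.6%, 82.2% and 65.2% with the higher floor, without a floor, with centred arrays and with separate probe sets. The fraction of the DSS effect kept in DSSPAR, 0.74 in colon and 0.49 in liver, was 0.795 and 0.418 with the higher floor and 0.802 and 0.655 without a floor. The correlation between tissues, 0.21, was 0.0647 without a floor and 0.179 without probe sets of shared type. Where the alternative's construction does not show it, the cause was not tested.

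List medians that stood apart changed sign mostly with arrays centred on their medians. For colon DSSPAR against DSS they became 0.080 for heat shock, 0.054 for immediate early and 0.064 for smooth muscle genes. For colon DSSPAR against CON they became 0.24 for absorptive colonocyte, 0.032 for enteroendocrine, 0.11 for immediate early, 0.070 for prostaglandin and leukotriene, 0.067 for taurine and sulfur amino acid and 0.19 for junction genes. For liver DSSPAR against CON they became 0.0088 for fatty acid synthesis and 0.035 for fatty acid oxidation. The absorptive median was 0.046 with centring on probe sets above the floor, the prostaglandin median 0.20 with the higher floor and 0.045 with quantile normalization, and the junction median 0.062 without a floor. For these changes of sign the cause was not tested beyond the shift of the arrays' medians.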

Other observations

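The test of BMP-SMAD target genes and those of gene length were written before their results were seen.

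A few hormone genes of the colonic epithelium went opposite ways within a cell class that did not stand apart in DSS against CON (median -0.17, percentile 4.45). Of its 16 enteroendocrine markers 13 lay within 2-fold, while Insl5 was 2.92-fold and Pyy, the peptide YY gene, 2.66-fold higher, whereas Nts, the neurotensin gene, was at least 7.41-fold lower (log2 ratio -0.84 with the floor at the 75th percentile). Against CON, DSSPAR had Insl5 4.41-fold and Pyy 2.64-fold higher, and Gcg, the proglucagon gene, read 275.3 in CON, 508.3 in DSS and 746.5 in DSSPAR. Genes of regenerating epithelium were higher in DSS than in CON in 6 of 13 cases and lower in 1 (median 0.59, percentile 99.96), including the growth factor gene Ereg (9.14-fold), Ptgs2 (6.59-fold) and Sprr1a (3.55-fold). Of 11 MHC class II genes all lay above CON in DSS, 3 by 2-fold (median 0.82, percentile 99.98), with H2-DMa 3.10-fold higher (log2 ratio 0.49 with the floor at the 75th percentile).

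In liver, genes that differ between the sexes moved apart in DSS against CON in these male mice. Male-biased genes were lower in DSS than in CON in 6 of 15 cases and higher in none (median -0.86, percentile 0.0), led by Cyp4a12a (13.7-fold), Elovl3 (9.95-fold) and Ugt2b38 (7.64-fold). Female-biased genes were higher in 4 of 15 cases and lower in none (median 0.43, percentile 99.2), including Cyp17a1 (4.05-fold) and the lipoprotein lipase gene Lpl (3.26-fold). In DSSPAR the male-biased genes were lower than in CON in 4 of 15 cases (median -0.58, percentile 0.0), while the female-biased genes did not stand apart (3 of 14 higher and 1 lower, median -0.098, percentile 35.9). Unfolded protein response genes were higher in DSS in 5 of 29 cases and lower in none (median 0.47, percentile 99.99), for example Derl3 (2.71-fold, log2 ratio 0.82 with the floor at the 75th percentile) and Sdf2l1 (2.17-fold). Among circadian clock genes, which did not stand apart (median -0.086, percentile 29.7), Dbp and Cry2 were each 2.41-fold lower and Nfil3 2.21-fold higher in DSS than in CON.

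Hepcidin genes were low in the DSS liver although acute phase genes were high: Hamp, which inflammation is known to induce, was 2.52-fold lower than in CON and Hamp2 17.8-fold. Lower BMP-SMAD signalling, the other known driver of hepcidin, may account for this as a hypothesis. The 4 measured BMP-SMAD targets had a median log2 ratio of -0.74 (percentile 1.0), with Id1 at -0.78, Smad6 at -0.71 and Smad7 at -0.78, while Bambi was at 0.15. A list of 4 genes in 1 pair of pools is a narrow base.

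Log2 ratios followed gene length in the colon pairs and, with opposite sign, in the liver pairs with DSSPAR. In liver DSSPAR against DSS, 109 of 1576 genes up to 5 kb long were at least 2-fold lower and 26 higher, against 109 and 108 of 3302 genes over 50 kb, and the rank correlation with length was 0.0680, with 0.114 for DSSPAR against CON and only 0.0305 for DSS against CON. In colon, short genes tended to be higher: the correlations were -0.129 for DSS against CON, -0.0965 for DSSPAR against DSS and -0.207 for DSSPAR against CON, where 109 short genes were higher and 26 lower. No bounds were set beforehand for the colon pairs, so a length bias there was not tested. Mitochondrial and ribosomal protein genes alone do not account for the liver trend, as 99 of its 109 lower short genes were neither and the correlation stayed at 0.0646 without them. A length bias between the liver arrays, which could come from RNA quality, was not decided, as 0.0680 lay between the bounds set beforehand; the 3'/5' ratio of Actb was 2.63 in DSSPAR against 3.53 in DSS and 3.55 in CON and that of Gapdh 1.07 against 1.54 and 1.21, and no biological explanation was tested.

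Some further values stood out and were chosen after they were seen. The 18S ribosomal RNA control probe set read 6156 in colon CON, 4018 in colon DSS and 390.4 in colon DSSPAR, and 65530, 93320 and 58100 in the liver arrays. Ppy, the pancreatic polypeptide gene, read 52.99, 295.1 and 465.0 in colon CON, DSS and DSSPAR, unlike the enzyme genes of the pancreas. Hoxb6, a positional gene of the hindgut, was at least 7.07-fold lower than in CON in both the DSS and the DSSPAR colon, with log2 ratios of -0.77 with the floor at the 75th percentile.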
